A study of Mus musculus with 6 samples.

How the data were processed

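RNA of rhombomere 1 from E12.5 mouse embryos of the ICR (CD-1) strain was measured in 6 pools, 3 of Gata2 conditional mutants and 3 of controls, with 6 dissected pieces in a pool. Per the labels' protocols, RNA was extracted with Trizol and copied into biotin-labelled cRNA with a kit for Illumina arrays, and per the series' design text it was hybridised to Illumina Mouse WG-6 BeadChips. Groups were taken from the sample titles and source names.

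The authors deposited a table of probe intensity for 6 arrays, on a linear scale and without normalization per the file headers, in which each intensity column is followed by a detection p-value. This detection p-value, per the file headers, states for each probe and array whether the signal exceeds background. The submitters' processing notes name GenomeStudio 1.0; the role of that program is not stated further. The columns name the genotype and an array number (5R, 6R and 7R for controls, 1R, 2R and 3R for mutants) that appears in no sample title, so each column was used as a replicate of its group only; columns were not assigned to titled samples by their values. A second table deposited by the authors holds normalized intensity, also linear. Tested on the file, each of its columns had a median of 86.4, with values from 50.5 to 41307, and at least 98.3% of the sorted positions were equal between columns (relative tolerance 1e-06), as quantile normalization leaves them. All 6 intensity columns matched exactly 1 column of this table with a Spearman correlation of 1, while the highest other correlation was 0.950. Of its values, 99.7% were whole multiples of the file's last decimal place divided by 17, within 0.05 of a step, against 5.79% for a divisor of 6, as if 17 arrays had been normalized together. The other arrays of that set were not analysed here. The normalized table was used as an alternative only.

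Intensities were background-corrected and normalized with limma 3.58.1 in R 4.3.3 (neqc: normexp with the background estimated from the detection p-values, offset 16, quantile normalization, log2). The background correction widens the folds of dim genes and a larger offset narrows them, so their size depends on this choice. Probes with a detection p-value under 0.05 on at least 3 of 6 arrays were kept, 19936 of 45276. Gene names came from a platform annotation table: 34881 probes had 1 gene symbol, 18 had several and 10377 had none there and were left unnamed. Of the named probes 34803 matched the gene table of assembly GRCm38.p6, which changed 0 symbols. Among the kept probes, 16786 were named and 3150 were unnamed; all entered the fit, and genes were counted over named probes only. For each gene the probe with the highest mean over all 6 arrays was used, which left 10524 genes.

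The comparison, mutant minus control, was fitted with limma (lmFit, then eBayes with an intensity trend; 8.99 prior degrees of freedom), and p-values were adjusted over genes by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists, 27 with 318 distinct genes, were fixed before the data were examined. Of these genes 292 had a probe named here and 196 were measured, and the rest were not analysed here. Lists were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. A gene whose probe was not above background on all arrays of its dim group has a fold given as a lower bound under this background correction. This bound leaves out sampling error. Positions from the GRCm38.p6 gene table served only to find which genes neighbour Gata2; a two-sided Fisher's exact test compared the share of changed genes within 10 Mb with the share elsewhere.

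The rule for the genes named was also fixed before the data were examined: Gata2; in each direction the 12 genes with the largest change among those past the threshold whose groups do not overlap; up to 4 further members of each list past the threshold; a short set of genes of the GABAergic, serotonergic and glutamatergic lineages whatever their result; and, where fewer than 5 genes passed in a direction, the 8 with the smallest p there. List members that did not pass were chosen as examples after their values were seen.

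Alternatives chosen before the data were examined were no background correction, an offset of 50, median scaling, the authors' normalized table, no detection filter, a stricter one (p-value under 0.01 on all 3 arrays of a group), the mean of a gene's probes, no intensity trend, array weights, unmoderated statistics, leaving out each array in turn, a replicate block (not run on the intensity table, whose column names give no replicate number), a threshold of 0.1, counting probes, and the other set tests. Added after seeing the data were the block on the authors' normalized table, a fit without genes within 10 Mb of Gata2, and the Xist level as a covariate. A block by BeadChip was not run, because the sources used here tie no array to a chip.

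The procedure was tested on simulated data with this design, 200 changed genes among 10524 in 5 runs. It recovered 54.4% of changes of 0.5 on the log2 scale, 99.6% of changes of 1 and 100% of changes of 2 and 4, and 5.93% of its calls were false. A planted list was called in 100% of 20 runs, with 0.15 other lists called per run. There the serotonergic list was lowered by 0.5 on the log2 scale. All genes had equal noise and were independent of each other. These runs therefore do not give the error rate of list calls in the data, where members can be correlated. Simulated arrays carried no shared structure beyond the groups. They also held more changed genes than the 18 called in the data, which makes small changes easier to recover in the simulation. Their noise was drawn from limma's moderated variances, which differ less between genes than measured variances do. This can also make recovery look too high. Figures were drawn with matplotlib 3.10.9.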

Results

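Rhombomere 1 is the most anterior segment of the embryonic hindbrain, just behind the midbrain border, and it gives rise to GABAergic, glutamatergic and serotonergic neurons. The series compared this tissue at E12.5 between mouse embryos labelled as conditional mutants of Gata2, a zinc finger transcription factor of early neuronal precursors, and their controls. En1-cre, a recombinase expressed in the midbrain and rhombomere 1, was used to delete the floxed Gata2 sequence; the deletion itself is taken from the labels. Mutants carried 2 floxed alleles. The control samples are titled wildtype, but the series' design text describes them as En1-cre carriers with 1 floxed allele, so they are called controls here. Each group held 3 pools of 6 dissected pieces, called biological replicates in that text, and each pool was hybridised to 1 Illumina Mouse WG-6 BeadChip array, which measures RNA as the brightness of beads carrying gene probes. Between 19388 and 20407 of 45276 probes, 42.8% to 45.1%, were above background on an array. The raw median intensity lay between 69.8 and 76.7. Correlations of the normalized values were 0.988 to 0.993 within groups and 0.988 to 0.991 between groups, across probes, which are not independent replicates. The number of arrays limits the precision. All differences below are mutant minus control on the log2 scale, with standard errors from limma, and n is 3 pools per group.

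The targeted gene was read first. The only probe named for Gata2 was not lower in the mutants. Its mean was 10.53 ± 0.16 in controls and 10.89 ± 0.17 in mutants (SD, n = 3), a difference of 0.36 ± 0.12 with a limma adjusted p of 0.412 after Benjamini-Hochberg adjustment (unadjusted p = 0.00907). All 3 mutant values lay above all 3 control values. The place of this probe relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part checks nothing, so the Gata2 signal neither bears out the labels nor goes against them.

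The main question was which genes differ between control and mutant rhombomere 1. Of the 4 largest decreases by measured value, 3 were in genes of serotonergic neurons; several probes were not above background in the mutants, so the order of the decreases is not settled. Tph2, the rate-limiting enzyme of serotonin synthesis in the brain, was at least 26.4-fold lower in the mutants, and Slc6a4, the serotonin transporter, was at least 14.6-fold lower. Cryba2, a beta-crystallin, fell by at least 3.91 in log2, and Slc17a8, a vesicular glutamate transporter also carried by serotonergic neurons, was 8.40-fold lower. Without background correction these genes were called too, but Tph2 was measured as 13.9-fold, Slc6a4 6.91-fold, Cryba2 7.76-fold and Slc17a8 5.92-fold lower. These ratios count background as signal and are no exact folds. In all, 18 of 10524 tested genes changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), of which 14 fell and 4 rose. In each of the 18 the 3 mutant values lay on one side of the 3 control values, which held for 1488 tested genes, 14.1%, where chance gives 10%. At an unadjusted p under 0.05 there were 929 genes, 472 lower and 457 higher, against 526 that chance alone would give. The count of changed genes was 52 without mutant array 1R, with 13 higher and 39 lower, and 12 without control array 5R, of which 11 were among the 18. Of 29 changed probes, 4 were unnamed here, and all 4 were lower in the mutants.

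**Figure D1:**
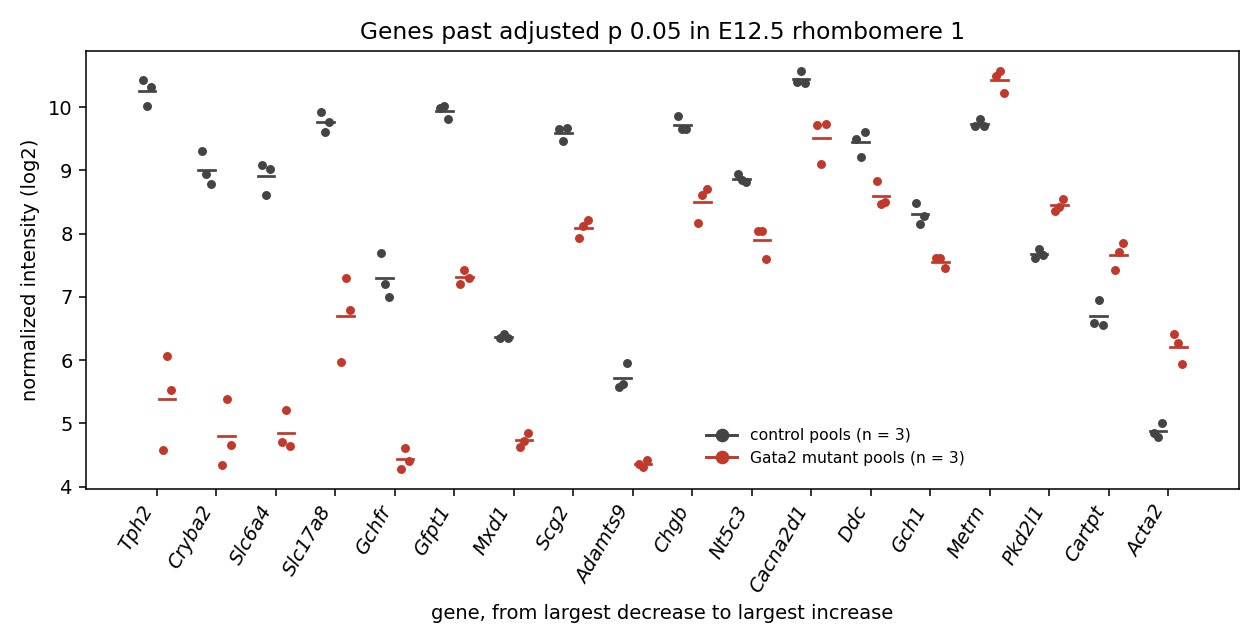
Normalized intensity (log2) of the 18 genes that changed at an adjusted p under 0.05, for the 3 control pools and the 3 Gata2 mutant pools; points are pools and short lines are group means. For every gene shown the 2 groups do not overlap. The widest distance between measured means was that of Tph2, with 10.25 in controls and 5.39 in mutants. Several probes were not above background in the mutants, so the order of the decreases is not settled.

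Of the 13 genes fixed beforehand as serotonergic neuron genes, 9 were measured, and 6 of these fell, the same count of 6 when adjusted over the list alone. Tph2 fell by at least 4.72 on the log2 scale (adjusted p = 4.61e-07), with measured means of 10.25 ± 0.21 and 5.39 ± 0.76 (SD, n = 3), and was above background on 2 of 3 mutant arrays. Slc6a4 fell by at least 3.87 (adjusted p = 3.83e-08), with measured means of 8.91 and 4.85, and was above background on 1 of 3 mutant arrays, while its second probe, above background on 0 of 3 mutant arrays, fell by at least 2.59. Slc17a8 fell by 3.07 ± 0.24 (adjusted p = 1.78e-05) and stayed above background on all 3 mutant arrays. Gchfr, the feedback regulator of the enzyme that Gch1 encodes, was at least 5.03-fold lower (adjusted p = 1.71e-06), with measured means of 7.30 and 4.43. Its probe was above background on 0 of 3 mutant arrays. A change written as at least a value is a lower bound for a probe that was not above background on all arrays of the dim group. Each value of that group was raised to at least the lowest signal above background on its array. The bound refers to the probe used and to the background-corrected values, and it leaves out sampling error. The 95% interval of the measured difference reached -4.27 for Tph2, -3.67 for Slc6a4, -3.72 for Cryba2 and -2.47 for Gchfr. For Tph2, Slc6a4 and Cryba2 these are smaller falls than the bounds. Without background correction, with background counted as signal, Gchfr was measured as 3.35-fold lower, which is no exact fold. A second Gchfr probe, above background on 2 of 3 mutant arrays, was also lower (unadjusted p = 5.84e-06). Ddc, which makes serotonin and dopamine from their precursors, was 1.79-fold lower (adjusted p = 0.0205), and its 3 probes gave differences of -0.84 to -0.87. Gch1, which starts the synthesis of the cofactor tetrahydrobiopterin, was 1.68-fold lower (adjusted p = 0.0265). The members that did not pass were the vesicular monoamine transporter Slc18a2 at -0.38, Maob at -0.36 and the transcription factor Lmx1b at 0.13. All of these were close to background in both groups. The control and mutant means were 5.27 and 4.90 for Slc18a2, 5.21 and 4.85 for Maob, and 4.93 and 5.06 for Lmx1b. With little room to fall, these values cannot show that the genes were spared. The list as a whole was lower by limma's camera test (median -0.84, adjusted p = 1.80e-23, and 0.132 with an estimated correlation). The fry test asks whether the members' average change differs from 0, without other genes for comparison, and it gave an adjusted p of 0.0103. Gch1 did not pass in 10 of the 19 alternative fits, and Ddc in 6 of them.

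Outside the serotonergic list, 8 genes fell. Cryba2 fell by at least 3.91 (adjusted p = 3.45e-07), with measured means of 9.01 and 4.80, and was above background on 1 of 3 mutant arrays. Scg2 and Chgb, granin proteins of dense-core secretory vesicles, were 2.84-fold and 2.34-fold lower (adjusted p = 1.37e-05 and 0.000902). Cacna2d1, an auxiliary subunit of voltage-gated calcium channels, was 1.90-fold lower (adjusted p = 0.0243), and Nt5c3, a pyrimidine nucleotidase, was 1.95-fold lower (adjusted p = 0.00575). Gfpt1, which opens the hexosamine pathway, fell by 2.63 ± 0.11, a 6.19-fold decrease (adjusted p = 3.83e-08), from 9.94 ± 0.10 to 7.31 ± 0.11 (SD, n = 3). The transcriptional repressor Mxd1 was at least 2.65-fold lower (adjusted p = 3.81e-05), with means of 6.37 and 4.73, and the secreted metalloprotease Adamts9 was at least 1.68-fold lower (adjusted p = 0.000902), with means of 5.72 and 4.36. The Mxd1 and Adamts9 probes were above background on 0 of 3 mutant arrays. Without background correction, with background counted as signal, their decreases were measured as 1.79-fold and 1.71-fold, which are no exact folds. With the mean of its detected probes Gfpt1 differed by -1.32. Cacna2d1 did not pass in 7 of 19 alternative fits and Nt5c3 in 2. Gfpt1, Mxd1 and Adamts9 lie on chromosome 6 within 10 Mb of Gata2 itself (gene order from assembly GRCm38.p6). There, 3 of 106 tested genes changed, against 15 of 10407 tested genes elsewhere (odds ratio 20.1, 95% interval 3.68 to 72.9, two-sided Fisher's exact p = 0.000728). On the whole chromosome 4 of 528 tested genes changed, the other being Nt5c3, which lies farther than 10 Mb from Gata2. A second detected probe for Gfpt1, close to background with a mean of 4.88, gave a difference of -0.00 (95% interval -0.35 to 0.34).

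Acta2, smooth muscle actin, was at least 2.35-fold higher in the mutants (adjusted p = 0.00132), with measured means of 4.88 in controls, where it was above background on 0 of 3 arrays, and 6.21 in mutants. Without background correction, with background counted as signal, the increase of Acta2 was measured as 1.59-fold. The 95% interval of its measured difference reached down to 0.99, a smaller rise than the bound of 1.23 in log2. The other 5 Acta2 probes were below the detection filter and differed by -0.09 to 0.23, so the increase rests on a single probe. So close to background, these probes neither bear out the increase nor go against it. Cartpt, the precursor of the CART neuropeptides, was 1.95-fold higher (adjusted p = 0.0205). Pkd2l1, a channel protein of neurons that contact the cerebrospinal fluid, was 1.70-fold higher (adjusted p = 0.0109), and Metrn, a secreted glial and neuronal factor, was 1.61-fold higher (adjusted p = 0.0205). Cartpt and Metrn each did not pass in 7 of 19 alternative fits, and Pkd2l1 in 5. Because only 4 genes rose, the others among the 8 smallest p-values were also read, and none of these passed with all 6 arrays and the detection filter: Tmem121 at 0.79 (adjusted p = 0.0802), Hps1 at 0.75 (adjusted p = 0.0790), the cadherin Celsr2 at 0.52 (adjusted p = 0.0802) and Ldha at 0.48 (adjusted p = 0.106). Hps1 was 0.36 without background correction, Tmem121 passed without the detection filter, and Celsr2 without mutant array 1R. Of the 4 rises only Acta2 was still called without control array 5R or control array 7R, only Acta2 and Pkd2l1 without mutant array 2R, and only Acta2 and Metrn without mutant array 3R. Without mutant array 1R all 4 were called among 13 rises.

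A further question was whether the GABAergic lineage that Gata2 serves in other parts of the brainstem and spinal cord was altered. With all 6 arrays, no single gene of its 2 lists passed over all genes tested. Of the 9 transcription factors fixed for V2b-type GABAergic precursors, 7 were measured, 0 passed, and 1 fell when adjusted over the list alone, Gata3, a paralog of Gata2. Gata3 differed by -0.85 ± 0.20 (adjusted p = 0.221), from 9.71 ± 0.26 to 8.86 ± 0.48 (SD, n = 3), and it passed without mutant array 3R, at -1.10 (adjusted p = 0.0132). Tal1 differed by -0.35 (adjusted p = 0.572; -0.56 to -0.21 leaving out 1 array) and Tal2 by -0.24 (adjusted p = 0.660; -0.32 to -0.16 leaving out 1 array). Sox14 differed by -0.42, Zfpm2 by -0.25 and Lmo4 by -0.24, and Foxn4 alone was positive at 0.28. As a list they were lower (median -0.25, camera adjusted p = 0.00587; adjusted p = 0.496 with an estimated correlation). Without mutant array 1R the adjusted p of this list was 0.157.

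Of the 10 genes fixed for GABAergic and glycinergic transmission, 6 were measured, 0 passed, and 1 fell when adjusted over the list alone, Gad1, which makes GABA from glutamate. Gad1 differed by -0.37 ± 0.12 (adjusted p = 0.386) and its paralog Gad2 by -0.22 ± 0.10 (adjusted p = 0.567), with -0.31 to -0.14 for Gad2 leaving out 1 array. The vesicular GABA transporter Slc32a1 differed by -0.19 ± 0.21 (adjusted p = 0.836), and its sign turned to 0.07 without mutant array 2R. All 6 measured members were negative, and as a list they were lower (median -0.21, camera adjusted p = 0.00305; adjusted p = 0.496 with an estimated correlation).

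No gene of the 2 lists fixed for glutamatergic neurons passed; this is the alternative fate of such precursors in other regions. Of the 7 fixed V2a-type genes, 6 were measured and 0 passed, over all genes or adjusted over the list alone. Slc17a6, the main vesicular glutamate transporter of the brainstem, differed by 0.02 ± 0.13 (adjusted p = 0.975), with means of 11.38 and 11.40. Its value was -0.13 without control array 5R and -0.02 without mutant array 2R. Vsx1 differed by 0.37 and Nkx6-1 by 0.33, and Lhx4 by -0.22. The list had a median of 0.07 (camera adjusted p = 0.404; adjusted p = 0.519 with an estimated correlation). Rhombic lip and other glutamatergic genes, of which 3 of 13 were measured, had a median of 0.04 (adjusted p = 0.981).

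**Figure D2:**
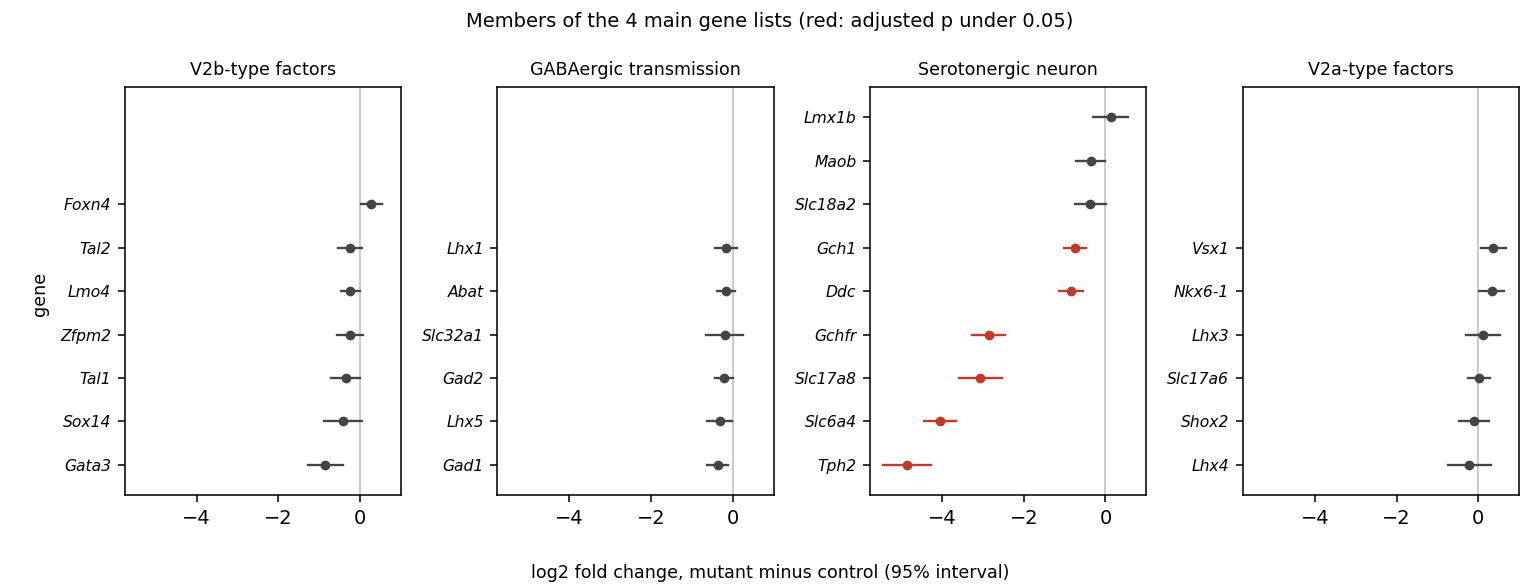
Log2 fold change, mutant minus control, with its 95% interval for the measured members of the 4 main gene lists; red marks an adjusted p under 0.05. In the serotonergic list 6 of 9 members are red and all 6 are negative, while all members of the other lists are grey.

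Progenitor and proliferation genes were read as the cells from which these neurons arise. Of 10 measured proliferation genes 9 were positive, with 0 passing over all genes or adjusted over the list alone, and examples were Tyms at 0.31, Mcm3 at 0.26 and Cdk1 at 0.23. The list was higher (median 0.17, camera adjusted p = 0.00587; adjusted p = 0.496 with an estimated correlation), but not without control array 6R (adjusted p = 0.359) or mutant array 1R (adjusted p = 0.144), nor by fry (adjusted p = 0.418). Ventral patterning and proneural factors had a median of 0.13 (14 measured, 0 passed, adjusted p = 0.0732), with Foxa2 at 0.65 the 1 member that rose when adjusted over the list alone and Nkx2-2 at 0.37 (adjusted p = 0.513). This list passed without control array 5R (adjusted p = 0.0108), control array 7R (adjusted p = 0.00685) or mutant array 2R (adjusted p = 0.0290). It also passed with the stricter detection filter (0.0277), the mean of each gene's probes (0.0197) and the Xist covariate (0.0487). With an estimated correlation its camera adjusted p was 0.496. Notch pathway genes had a median of 0.06 (10 measured, adjusted p = 0.179) and neural progenitor genes a median of -0.00 beside a mean of 0.07 (11 measured, adjusted p = 0.356). In both, Hes5 at 0.37 was the 1 member that rose when adjusted over the list alone. Genes of the isthmic organiser and of the FGF response had a median of 0.32 (12 measured, adjusted p = 0.140), with Fgf8 at 0.41 and Fgf17 at 0.43. Etv4 at 0.52 was the 1 member that rose when adjusted over the list alone. Its means, 4.70 in controls and 5.21 in mutants, were close to background. The isthmic and FGF list had a camera adjusted p of 0.0238 without control array 7R, 0.0444 without the detection filter and 0.496 with an estimated correlation.

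Other neuronal groups did not pass as lists. Pan-neuronal genes had a median of -0.08 (11 measured, adjusted p = 0.101), among which the synaptic vesicle protein Syt1 at -0.62 (adjusted p = 0.0614) fell when adjusted over the list alone, the 1 member to do so. The list's adjusted p was 0.0247 without control array 7R. Neuropeptide genes had a median of -0.22 (9 measured, adjusted p = 0.179): Cartpt rose, also when adjusted over the list alone, and the other 8, among them Tac1 at -0.29 and Pnoc at -0.28, were negative and did not pass. Noradrenergic and dopaminergic genes had a median of -0.20 (4 measured, camera adjusted p = 0.143, and 0.496 with an estimated correlation). Nr4a2 at -0.57 was the 1 member that fell when adjusted over the list alone, and it passed over all genes without mutant array 1R. The list's adjusted p was 0.00760 without control array 5R. Axon guidance genes had a median of -0.03 (20 measured, adjusted p = 0.189) and cranial motor neuron genes one of 0.05 (6 measured, adjusted p = 0.444).

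Markers of other tissues that a dissected piece can hold were compared in the same way. Erythroid genes were higher as a list (8 measured, 7 positive, median 0.17, camera adjusted p = 0.0471; adjusted p = 0.496 with an estimated correlation). With all 6 arrays 0 of them passed over all genes, and 2 embryonic globins, Hbb-bh1 at 0.53 and Hba-x at 0.41, rose when adjusted over the list alone. Both globins passed over all genes without mutant array 1R. The call of the list was lost without control array 6R (adjusted p = 0.330), control array 7R (0.0740), mutant array 2R (0.0638) or mutant array 3R (0.214). It was also lost with median scaling (0.114), without the intensity trend (0.0843) and by fry (0.443). Pericyte and smooth muscle genes, to which Acta2 belongs, had a median of 0.10 (6 measured, 1 rose, adjusted p = 0.356), and Rgs5 at -0.35 and Kcnj8 at -0.33 were negative. By the fry test this list had an adjusted p of 0.0493, with Acta2 the 1 member that rose when adjusted over the list alone. Microglia genes had a median of -0.07 (8 of 10 measured, adjusted p = 0.356) and endothelial genes 0.01 (11 of 12 measured, adjusted p = 0.988). Meningeal genes had a median of -0.06 (3 of 12 measured, adjusted p = 0.981) and neural crest and ganglion genes 0.04 (5 of 10 measured, adjusted p = 0.935). Choroid plexus genes had a median of 0.01 beside a mean of -0.05 (3 of 7 measured, adjusted p = 0.789). Genes of the neighbouring midbrain and forebrain had a median of -0.03 (4 of 8 measured, adjusted p = 0.603) and those of the posterior hindbrain 0.07 (2 of 11 measured, adjusted p = 0.956). The 2 posterior hindbrain genes, Hoxa2 and Hoxb2, had group means of 4.89 to 5.40, close to background. Lists with so few measured members cannot show that dissection or tissue content was equal. For the endothelial and posterior hindbrain lists the camera test leaned down while median and mean were above 0. Immediate early and heat shock genes had a median of -0.08 (adjusted p = 0.0900) and p53 response genes 0.10 (adjusted p = 0.603). The sex-linked list had a median of -0.12 (adjusted p = 0.603), and the mean of the Xist probes, RNA of the inactive X chromosome, was 8.55, 7.83 and 8.56 in control arrays 5R, 6R and 7R and 9.02, 8.43 and 7.15 in mutant arrays 1R, 2R and 3R. With this Xist level as a covariate, added after seeing the data, 20 genes changed, among them all 18 above. The Y-linked gene Kdm5d was 5.75, 5.59 and 5.74 in control arrays 5R, 6R and 7R. In mutant arrays 1R, 2R and 3R it was 4.68, 6.02 and 6.02. Uty, also Y-linked, was 5.38 to 5.41 in controls and 5.21 to 5.51 in mutants. Whether the pools differed in sex was not tested.

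Over the 27 lists, 5 passed by camera with the preset correlation of 0.01, 3 lower and 2 higher, and 0 with an estimated correlation, where the smallest adjusted p was 0.132 for the serotonergic list. With 3 arrays against 3, differences of 0.5 on the log2 scale were recovered for 54.4% of simulated changed genes, and those of 1 for 99.6%. The simulation held 200 changed genes, while 18 were called here. With fewer changed genes the same adjusted threshold demands a smaller unadjusted p, so these shares can be too high for these data. The simulated noise, drawn from moderated variances, can raise them further.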

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

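The run of the replicate block on the authors' table, the fit without genes near Gata2 and the Xist covariate were chosen after the results were seen; the other settings were chosen before. The 18 changed genes gave 339 pairs of gene and setting, with the same call in 284, no call in 55 and a reversed direction in 0. All 18 stayed called without background correction, with offset 50 and in the authors' table, with smaller folds for dim genes: Tph2 was -3.80 without background correction and -3.96 in the authors' table, Slc6a4 -2.79 and -2.87, Cryba2 -2.96 and -3.04. Unmoderated statistics with 4 degrees of freedom called 0 genes, 0 higher and 0 lower (867 at an unadjusted p under 0.05, smallest adjusted p 0.0825), and 29 probes changed in place of 18 genes. Without the intensity trend 2 genes were higher. Leaving out 1 array gave 12 to 52 changed genes (12 without control array 5R, 52 without mutant array 1R), 2 to 13 higher and 10 to 39 lower, with 13 and 39 without 1R and 2 higher without 5R, 7R or 2R (of the 4 rises, 1 was kept without 5R or 7R and 2 without 2R or 3R); all 18 stayed called without 1R. The cause of these differences was not tested. The Gata2 value stayed between 0.26 and 0.45. The names of the scanner columns carry no replicate number, so the replicate block was run on the authors' table only: 14 genes changed, 2 of them higher. Same-numbered samples correlated at -0.30 to -0.04 in their deviations, and 0 of 6 samples correlated best with their own number, so the block is not read as a pairing. A block by chip was not run.

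With an estimated correlation the adjusted p was 0.496 for the V2b-type list, 0.496 for the GABAergic list and 0.132 for the serotonergic list, and with fry 0.436 for the V2b-type and 0.300 for the GABAergic list. Leaving out 1 array gave 1.04e-05 to 0.157 for the V2b-type list (0.157 without 1R), 3.86e-05 to 0.0290 for the GABAergic, 1.19e-29 to 2.07e-19 for the serotonergic and 0.174 to 0.742 for the V2a-type list. Of the other lists 2 were called, against 1 with median scaling, 1 without trend, 0 with an estimated correlation, 1 with fry and 0 to 4 when leaving out 1 array (4 without 5R or 7R, 0 without 6R, 1 without 1R or 3R). Lists that turned direction were never called. Their adjusted p were, for the rhombic lip, 0.996 without background correction, 0.996 with offset 50, 0.920 with median scaling, 0.988 in the authors' table, 0.928 without filter, 0.965 with the replicate block, 0.943 with Xist and 0.359 to 0.936 leaving out 1 array. For the endothelium they were 0.996, 0.996 and 0.988 in the same order (no background correction, offset 50, authors' table), 0.960 with the mean of probes, 0.961 without trend, 0.913 with fry, 0.960 with the replicate block and 0.441 to 0.991 leaving out 1 array. Others were the posterior hindbrain (0.765 without filter, 0.918 with array weights, 0.530 to 0.867), choroid plexus (0.740 without filter, 0.981 with the mean of probes, 0.152 to 0.921), meninges (0.957 with the stricter filter, 0.809 to 0.936), cranial motor neurons (0.366 to 0.976) and neural crest (0.402 to 0.936). Slc17a6 ranged from -0.13 to 0.14 and Slc32a1 from -0.40 to 0.074 when 1 array was left out.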

Other observations

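Among the tests below, those of an exchanged array, of the place of the Gata2 probe, of a loss of serotonergic cells as the source of the neighbouring genes' fall, of a lower share of all neurons and of an equally large fall of dense-core vesicle genes were chosen only after the result was seen. The genes in the next paragraph were picked after their values were seen.

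Slc17a8, the serotonergic list's strongly lowered gene that stayed above background on all 3 mutant arrays, was 5.98, 7.30 and 6.79 on arrays 1R, 2R and 3R, against 9.60 to 9.92 in controls. Just short of the threshold, with adjusted p of 0.0614 to 0.0909 (limma, Benjamini-Hochberg), were the neuronal genes Syt1 at -0.62 and Cntn1 at -0.67, and Dydc2 at -0.84, Tbc1d16 at -0.75, Ehmt1 at -0.69 and Rhobtb2 at -0.54. Of 19 alternative fits, Syt1 passed in 6, Ehmt1 in 3, Dydc2 in 2, Tbc1d16 in 1, and Cntn1 and Rhobtb2 in 0. In total 27 genes lay at an adjusted p under 0.1.

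The count of 18 changed genes was set against the other splits of the 6 arrays into 3 and 3. Of 10 splits, 1 gave as many genes, the real one, and the highest other split gave 1 gene. A design of this size cannot give a share under 0.1.

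Gfpt1, Mxd1 and Adamts9, which fell, lie beside Gata2 on chromosome 6, Gfpt1 and Mxd1 within 2 Mb and Adamts9 within 5 Mb. Strain variants carried along with the floxed allele may account for this. Mutants have 2 copies of that allele and controls 1 per the series' design text, although the titles call the controls wildtype. Changed genes were enriched within 10 Mb of Gata2 (Fisher's exact p = 0.000728, odds ratio 20.1), and the most called in a window of that width on another chromosome was 2. A variant under the called probe alone cannot be told apart from lower expression, since only 1 other detected probe existed, for Gfpt1, and it lay nearer to 0 (100% of 1 probe) but close to background. A loss of serotonergic cells that express these genes cannot be told apart either, since cells and genotype change together; the smallest measured difference of the 3, -1.35 for Adamts9, had 0 of 3 mutant arrays above background and decides nothing. A regulatory effect of the Gata2 deletion on its neighbours, which the design would allow, was not tested.

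Gata2 itself was not lower in the mutants. An exchange of 1 array between the groups could contribute to this, but the lowest control value exceeded the highest mutant value by 3.95 for Tph2 and 3.39 for Slc6a4, which argues against it. An exchange of the whole groups would leave that gap as wide and was not tested. A probe outside the deleted part of the gene, with transcript remaining, could give the difference of 0.36, and it cannot be told apart from other explanations without the places of probe and deletion.

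Scg2 and Chgb, of dense-core vesicles, were 2.84-fold and 2.34-fold lower in the mutants. A lower share of all neurons may lower such genes. The pan-neuronal list had a median of -0.081 (bootstrap 95% interval over genes, not pools, -0.16 to 0.01). This argues against a lower share of all neurons by about the size of these falls. A smaller drop of that share stays open (8 of 11 measured pan-neuronal genes negative, camera adjusted p = 0.101). A fall of dense-core vesicle genes as a group by about the size of the Scg2 and Chgb falls is also argued against. The 10 of 13 others that were measured lay between -0.26 and 0.11, with a median of -0.07 (bootstrap 95% interval over genes, not pools, -0.17 to 0.02). A smaller shift of that group stays open (camera p = 0.155, and 0.407 with an estimated correlation). A loss of the serotonergic neurons, which the design would allow, was not tested for these 2 genes.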
